A study of Mus musculus with 6 samples.

How the data were processed

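Chromatin accessibility had been measured by ATAC-seq, which uses a transposase to cut open chromatin, in CD8 T cells sorted from tumours of mice that carried B16-F10, a mouse melanoma line. Per the labels' protocols, tumours were digested with collagenase and DNase, and live cells were sorted on CD8, Ly108 (SLAMF6) and PD-1. Genomic DNA was then prepared with a commercial ATAC-seq kit. The 6 libraries form 3 groups of 2, named here as in the labels: WT_Tprime, WT_Tex and K215M_Tex. WT is wild type, and K215M is a mutation of Card11, which encodes a scaffold protein that links antigen receptors to NF-kB. The labels do not spell out the 2 population names. Nothing in the labels says whether the 2 libraries of a group came from separate mice, so their spread may be technical.

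The deposited files are 6 peak lists, 1 for each library, so each library had its own peak calls. The submitters' processing notes name the genome build GRCm38.p6. The aligner, the peak caller and its settings are not given in the sources used here. Each list holds 10 columns without a header, and the deposited positions, lengths and summit offsets are whole base pairs (other columns, without a measured unit). The authors' fold column is a ratio of signal over background, and it ran from 1.488 to 25.97 over the 6 lists. The authors' significance columns are −log10 p and −log10 q values, and the lowest deposited −log10 q lay between 1.324 and 1.45 in each list. The deposited score column equals 10 times the −log10 q, rounded down, apart from at most 0.023% of the peaks of a list. These values belong to single peaks of 1 list and were used to describe, rank or filter peaks within that list. The files hold no read counts, so the depth of the libraries is unknown. A longer list can come from deeper sequencing as well as from more open chromatin.

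Peaks of all libraries on the 19 autosomes and X were merged where they overlapped by 1 bp or more, and a library was counted as having a region where a peak of its list touched it. The merging was tested against bedtools 2.31.1 and gave the same regions. A region was counted as group-specific where both libraries of one group had it and neither library of the other group did. These counts were set beside those of the 2 mixed splits of the same 4 libraries, in which each side held 1 library of each group. With 3 splits of 4 libraries no p-value under 0.333 can be reached, so none is given for the counts. Replicate numbers are shared between groups, but nothing in the labels ties equal numbers to a mouse, a day or a batch.

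A region was given to every protein-coding gene whose body it overlapped, or else to the nearest gene body within 100 kb, using the RefSeq gene table of GRCm38.p6, the same build as the peaks. The plan had been to use the nearest transcription start. The gene table used here has no strand, so gene bodies took its place, and no exon or promoter is named. Of 127935 regions, 95.0% went to a gene and 61.7% lay in a gene body. The planned comparison of 26 transcription factor motifs needs the genome sequence, which was not used here, and it was not run.

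For each gene with 5 or more group-specific regions, a two-sided exact binomial test compared the split of these regions with the split over all genes, with Benjamini-Hochberg adjustment over all genes tested. For each of 17 gene lists, the net share was the number of regions specific to the first group minus the number specific to the second, divided by all regions of the list. A region given to several genes counts once for each. The net share was compared with 10000 random gene lists matched on regions per gene (a two-sided permutation test over genes, adjusted over the lists of a comparison, and 0.0001 is the smallest p it can give). An adjusted p of 0.05 was the threshold. Regions and genes, not libraries, are the units of both tests, so they show whether a gene or list stands apart from others in these libraries. The lists covered stem-like progenitors, terminal exhaustion, effector and cytotoxic genes, NF-kB members and targets, CARD11-BCL10-MALT1 and T cell receptor signalling, NFAT, NR4A, EGR and AP-1 family factors, cytokine and chemokine receptors, tissue residency, interferon response and the cell cycle. Lists for other cell types covered melanoma cells, macrophages and other myeloid cells, B cells, natural killer cells, CD4 and regulatory T cells, fibroblasts and endothelium, and hepatocytes. Of their 373 entries, 370 matched the gene table. Lists of T cell identity genes and dendritic cell genes were added after the data were seen. The dendritic cell list is used in the closing section alone. The T cell identity list is also used for K215M_Tex versus WT_Tex and among the results flagged for a closer look.

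In simulated calls with no gene effect, no gene passed in any of the 3 comparisons, and between 3.0% and 4.0% of random lists had p below the 0.05 level. The direction of each region was drawn independently, as the exact binomial test assumes. The simulations therefore cannot show how often genes pass where neighbouring regions change together. A strong shift toward the second group was then given to 200 genes with at least 8 group-specific regions, and 144 were called in the setting of WT_Tex versus WT_Tprime and 182 in that of K215M_Tex versus WT_Tprime. With at least 12 regions per gene, 162 and 198 of 200 were called. In the setting of K215M_Tex versus WT_Tex, 26 genes with at least 8 such regions could be shifted and 25 were called. Shifts toward the first group, and genes with fewer than 8 regions, were not simulated.

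Comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took list genes past the threshold, then Cd8a, Slamf6, Pdcd1, Card11, Tcf7, Tox and Havcr2, then the 5 genes of each direction outside the lists with the lowest p. After these came the 2 genes of each T cell list with the most group-specific regions of each direction, up to 30 genes a comparison. For K215M_Tex versus WT_Tprime it took the fixed 7 genes. Other named genes fall outside the rule and were chosen after their values were seen. They are Adgre1, Tyrp1, Dct, Tyr, Kit, Gpnmb, Itgam, Pax5, Kdr, Xist, the Y-linked genes and the stem-like genes named for K215M_Tex versus WT_Tprime. Single regions were the 5 of each direction with the highest −log10 q in the weaker library. Alternatives covered a −log10 q of at least 5, the same number of peaks from every library (the strongest 64115 by −log10 p), and a call that needed 50% of the region covered. They also covered windows of 500 bp around summits, every sequence in the lists, other rules for giving regions to genes, each library left out, and a replicate block. A version on autosomes alone was added after seeing the data. Shares of regions carry Wilson 95% intervals, which cover counting error only. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.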

Results

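Accessible chromatin was profiled in 6 libraries of tumour-infiltrating CD8 T cells, 2 each of WT_Tprime, WT_Tex and K215M_Tex. The peak lists held 66287 and 64176 peaks for WT_Tprime, 75175 and 68409 for WT_Tex, and 83903 and 76398 for K215M_Tex (replicates 1 and 2). Peaks had a median length between 370 and 396 bp in each list. Merging gave 127935 regions, of which 32593 were called in all 6 libraries and 34747 in 1 library. Depth is unknown.

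The genotype of the Tex libraries is given in conflicting ways. For 4 of the 6 lists, all of them Tex, the names of the deposited lists and the peak identifiers inside them carry the other genotype than the sample labels. Groups are named here as labelled. The libraries labelled WT_Tex hold identifiers that start with KM3, those labelled K215M_Tex hold identifiers that start with WT3, and those labelled WT_Tprime hold identifiers that start with WT1. If the identifiers are right, every direction between WT_Tex and K215M_Tex turns round, and the populations of wild-type mice are those compared under K215M_Tex and WT_Tprime.

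Libraries separated more by sorted population than by genotype label. Y-linked signal also set WT_Tex apart from both other groups. Libraries of 1 group shared between 70.7% and 71.5% of the regions called in either. WT_Tex and WT_Tprime libraries shared between 42.4% and 44.2%, and K215M_Tex and WT_Tprime libraries between 37.9% and 39.2%. The Tex libraries of different label shared between 63.0% and 66.0%, which lies below the replicate pairs. The same order held with the same number of peaks from every library.

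**Figure D1:**
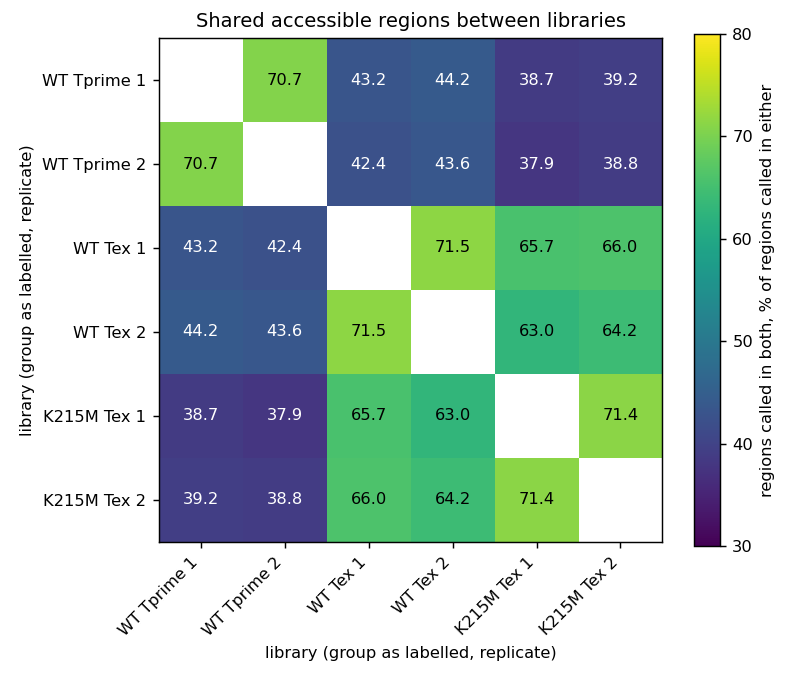
Heatmap of the regions called in both libraries as a percentage of the regions called in either, for each pair of the 6 libraries (rows and columns, by group as labelled and replicate, and the blank diagonal is each library with itself). Replicate pairs reach 70.7% to 71.5%, Tex libraries of different label 63.0% to 66.0%, and pairs of a Tex and a WT_Tprime library 37.9% to 44.2%.

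The comparison of WT_Tex with WT_Tprime asks how chromatin differs between the sorted populations. These groups also differ in Y-linked signal, which cannot be told apart from population here. The genes Ddx3y, Eif2s3y, Uty and Kdm5d had 7 peaks in each WT_Tex library and 0 in the WT_Tprime libraries. If the identifiers are right, the groups differ in genotype too. Both libraries labelled WT_Tex and neither WT_Tprime library had 16758 regions, and the reverse held for 14094 regions. The sum of 30852 was 28.7% of the regions called in any of the 4 libraries. The mixed splits of the same libraries gave 1236 and 1118 regions. Regions at Tox, which encodes a transcription factor of exhausted CD8 T cells, were called far more often in WT_Tex, and regions at Foxp1, a forkhead factor, far more often in WT_Tprime. Without WT_Tex replicate 2 the WT_Tex-only count was 27841, and without WT_Tprime replicate 2 the WT_Tprime-only count was 21671, since 1 library then decided a call.

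Among the terminal exhaustion genes, Tox (chromosome 4, 6686353 to 6991557) had 27 regions specific to WT_Tex and none specific to WT_Tprime (exact binomial test, adjusted p = 8.11e-05). The WT_Tex libraries had 50 and 45 regions there and the WT_Tprime libraries 12 and 14. Ikzf2, which encodes Helios, had 8 and none, with an adjusted p of 0.115 over all genes by the exact binomial test. Of the 8 genes of the list that could be tested, 1 passed over all genes and 2 passed adjusted over the list alone, Tox and Ikzf2. Pdcd1, the gene of the sort marker PD-1, had 2 WT_Tex-only regions and no WT_Tprime-only region. Havcr2, the gene of the checkpoint receptor TIM-3, had 2 and 1. Id2, a regulator of effector differentiation, leaned to WT_Tprime with 1 against 6, and Prdm1, which encodes Blimp-1, had 4 and 5. Neither Id2 nor Prdm1 passed (exact binomial tests, adjusted p = 0.235 and 0.916). The list as a whole had 71 WT_Tex-only and 28 WT_Tprime-only regions and did not pass (permutation test over genes, adjusted p = 0.111). It passed at 0.011 where regions were given to genes within 20 kb and at 0.0153 with gene bodies and 10 kb on both sides. Without WT_Tprime replicate 2 it passed at 0.0204 (permutation tests).

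**Figure D2:**
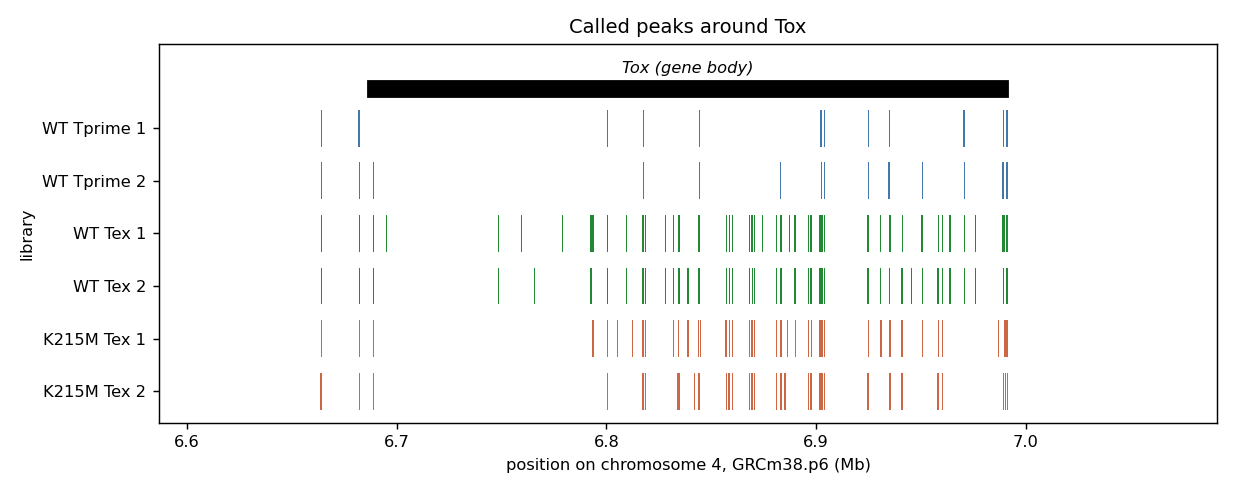
Map of the called peaks of each library (coloured ticks, 1 row per library, drawn at least 600 bp wide) around Tox on chromosome 4 of GRCm38.p6, with position in Mb and the gene body in black. The WT_Tex libraries had 50 and 45 of the gene's regions, the K215M_Tex libraries 41 and 33, and the WT_Tprime libraries 12 and 14.

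The stem-like progenitor genes leaned to WT_Tprime, with 41 WT_Tex-only and 63 WT_Tprime-only regions, and the list did not pass (permutation test over genes, adjusted p = 0.228). Satb1, a chromatin organiser, had none and 8 (exact binomial test, adjusted p = 0.0579 over all genes and 0.0152 adjusted over the list alone). It was the 1 gene of 8 tested that passed adjusted over the list alone, and none passed over all genes. Bach2, a repressor of effector differentiation, had 6 and 16, and Cd28, a co-stimulatory receptor, 7 and 1 (exact binomial tests, adjusted p = 0.15 and 0.281). Slamf6, the gene of the sort marker Ly108, had 2 WT_Tprime-only regions, and Tcf7, which encodes TCF-1, had 1. Neither had a WT_Tex-only region. Cd8a had 2 WT_Tex-only regions and none of the other kind.

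At Card11 itself (chromosome 5, 140872999 to 141000596), 1 region was specific to WT_Tex and 11 to WT_Tprime. The WT_Tprime libraries had 34 and 33 regions there and the WT_Tex libraries 21 and 19. The exact binomial test gave an adjusted p of 0.0579 over all genes and 0.0134 adjusted over the list alone, and 0.0213 over all genes with the same number of peaks from every library. Card11 was the 1 gene of 7 tested in its signalling list that passed adjusted over the list alone. That list as a whole had 55 and 50 regions (permutation test over genes, adjusted p = 0.906). NF-kB members and targets had 50 WT_Tex-only and 33 WT_Tprime-only regions and did not pass either (permutation test, adjusted p = 0.87). Tnfaip3, an inhibitor of NF-kB, had 7 and 3, Cd83 had 6 and 2, and Nfkb1 had 4 and 6. No gene of this list passed over all genes or adjusted over the list alone. Among effector and cytotoxic genes, Ifng had 5 and 1, Klf3 had 5 and 6 and Klre1 had 1 and 2. The list had 31 and 19 regions (permutation test, adjusted p = 0.87), and none of its 3 tested genes passed.

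Of the 7 lists of other cell types, 1 passed. Macrophage and other myeloid genes had 5 WT_Tex-only and 47 WT_Tprime-only regions, the 1 list of 17 that passed (permutation test over genes, p = 0.0001, the smallest it can give, adjusted p = 0.0017). The WT_Tprime libraries had 114 and 121 regions at these genes and the WT_Tex libraries 69 and 63. Flt3, a receptor of dendritic cell precursors, had 10 WT_Tprime-only regions and none of the other kind (exact binomial test, adjusted p = 0.0293, and 0.0713 with the same number of peaks from every library). Adgre1, which encodes the macrophage antigen F4/80, had 5 and none, and with Flt3 passed adjusted over the list alone. Melanoma genes leaned the other way, with 52 WT_Tex-only and 21 WT_Tprime-only regions (permutation test, adjusted p = 0.0978, and 0.0493 without WT_Tex replicate 1). Each of the 16 melanoma genes had at least 1 WT_Tex-only region, where random lists had 10.1 such genes on average. Tyrp1 had 6 WT_Tex-only regions and no WT_Tprime-only region, Tyr 3 and none and Dct 6 and 2, while Kit, with 1 and 6, and Gpnmb, with 1 and 4, ran the other way. The WT_Tprime libraries had 60 and 52 regions at melanoma genes and the WT_Tex libraries 100 and 97.

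The other 10 lists did not pass (permutation tests, adjusted p from 0.228 to 0.993). B cell genes had 8 WT_Tex-only and 16 WT_Tprime-only regions, natural killer cell genes 5 and 11, and fibroblast and endothelial genes 12 and 24. CD4 and regulatory T cell genes had 18 and 12, and hepatocyte genes 4 and 3. The NFAT, NR4A, EGR and AP-1 family had 79 and 66, cytokine and chemokine receptors 29 and 39, and tissue residency genes 29 and 35. Interferon response genes had 7 and 4 and cell cycle genes 15 and 16. With gene bodies and 10 kb on both sides the B cell list passed (permutation test, adjusted p = 0.0465).

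Over all genes, 36 of 1778 tested passed, 14 toward WT_Tex and 22 toward WT_Tprime (exact binomial tests). As the test is set against the overall share of 54.3%, 229 genes had enough regions to reach the highest p called toward WT_Tex and 514 toward WT_Tprime. Outside the lists, the genes with the lowest p toward WT_Tex were Sox6, an SRY-related transcription factor, with 21 WT_Tex-only regions and no WT_Tprime-only region, Farp1 with 17 and none, Fmn1, a formin, with 18 and none, Rbms3, an RNA-binding protein, with 18 and none, and Snd1 with 23 and 2. Rbms3 had no region in either WT_Tprime library, 22 in each WT_Tex library and 35 and 36 in the K215M_Tex libraries. At each of these genes the counts were lowest in WT_Tprime and highest in K215M_Tex, the order also seen at melanoma genes. The K215M_Tex lists were also the longest, and which cells these regions come from was not tested. Toward WT_Tprime these were Foxp1 (chromosome 6, 98925342 to 99522746) with 8 and 41, Zfp366, a zinc finger gene of dendritic cells, with none and 16, Lpp with 4 and 25, Vav3, a Rho exchange factor, with none and 13, and Tbxas1, which encodes thromboxane synthase, with 2 and 18. Adjusted p over these 10 genes ran from 8.11e-05 for Foxp1 to 0.0109 for Snd1 (exact binomial tests).

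The strongest single region called in both WT_Tex libraries and no WT_Tprime library lay in Ubxn7 (chromosome 16, 32379345 to 32380061), with the authors' fold values of 16.4 and 15.0. Others lay in Stk39, Med15 and Ppp2r5d and 30102 bp from Nrp1. In the other direction it lay in Usp32 (chromosome 11, 85003424 to 85003938), with fold values of 16.5 and 15.6. Others lay in Nnmt, 6368 bp from Pip4k2a, near Runx3 and 88540 bp from Fyn. The region nearest to Runx3, which encodes a CD8 lineage factor, was 14739 bp from the gene (chromosome 4, 135192729 to 135193393).

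The comparison of K215M_Tex with WT_Tex asks what the Card11 mutation does to chromatin within the Tex population. It gave 6725 regions specific to the libraries labelled K215M_Tex and 2816 specific to those labelled WT_Tex. The identifiers in the lists give both groups the opposite genotype. The sum of 9541 was 9.3% of the regions called in any of the 4 libraries, against 2880 and 2340 for the mixed splits. Against this excess, 3 lists passed toward WT_Tex, those of stem-like, exhaustion and T cell receptor signalling genes, and Tox, Fyn and Cd69 had more WT_Tex-only regions. With the same number of peaks from every library the exhaustion list no longer passed, and the called genes fell from 8 to Fyn alone. T cell identity genes, a list chosen after the data were seen, shifted too, with 11 K215M_Tex-only and 35 WT_Tex-only regions (permutation test, p = 0.0001, not adjusted). Of its 27 genes, 10 belong to other lists. Without them the list lay at -4.03 SD from random lists with the same number of peaks. Other lists of T cell genes, such as effector genes and NF-kB members and targets, did not pass. K215M_Tex-only regions made up 70.5% of the group-specific regions. With the same number of peaks from every library they numbered 4250 against 3819, or 52.7%, and the mixed splits then gave 57.3% and 51.8%.

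**Figure D3:**
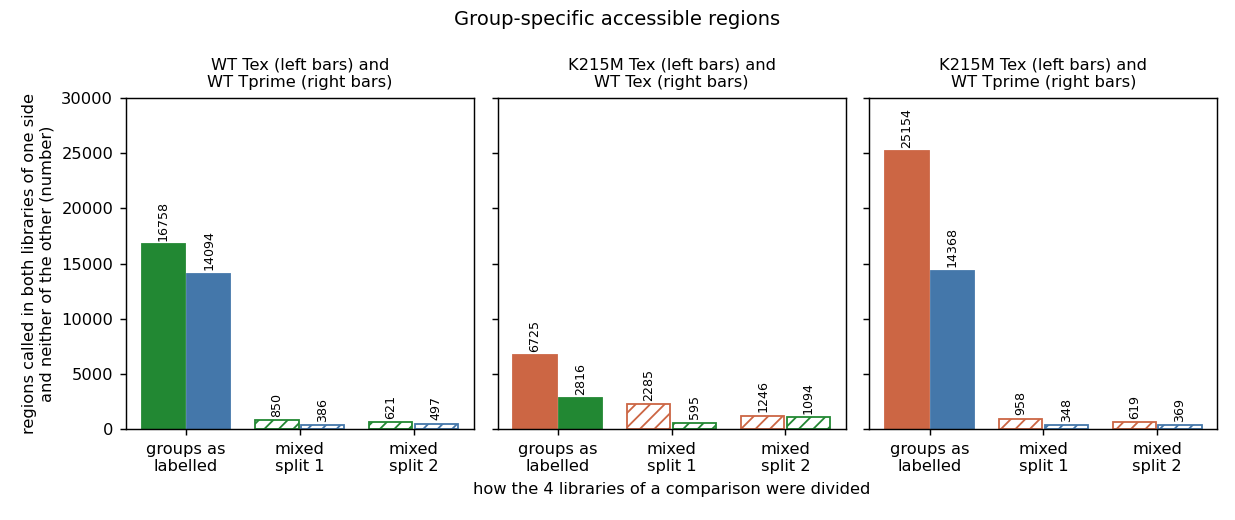
Bars give the number of regions (y axis) called in both libraries of one side and neither of the other, for the groups as labelled (filled) and for 2 mixed splits of the same 4 libraries with 1 library of each group on each side (hatched). The labelled groups gave 30852, 9541 and 39522 regions in all, and the largest sum of a mixed split was 1236, 2880 and 1306.

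Stem-like progenitor genes had 6 K215M_Tex-only and 19 WT_Tex-only regions, a net share of -2.79%, where random lists had 3.04% ± 1.55 (SD over lists). The permutation test over genes gave an adjusted p of 0.0034. S1pr1, the receptor for egress from tissue, had 3 WT_Tex-only regions, Tcf7 had 1, Foxo1 had 2 of each kind, Bach2 had 1 of each kind and Slamf6 had none of either. Terminal exhaustion genes had 2 and 15 (permutation test, adjusted p = 0.0034, and 0.0782 with the same number of peaks from every library). Tox had 8 WT_Tex-only regions and none of the other kind (exact binomial test, adjusted p = 0.00973). Ikzf2 had 2 and Havcr2 had 1 WT_Tex-only region, Bhlhe40 had 1 of each kind, Cxcr6 had 1 K215M_Tex-only region and Pdcd1 had neither. Tox was the 1 gene of this list with enough regions to be tested, and it also passed adjusted over the list alone. No stem-like gene had enough regions.

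The CARD11-BCL10-MALT1 and T cell receptor signalling genes had 17 K215M_Tex-only and 24 WT_Tex-only regions (permutation test, adjusted p = 0.0244). Fyn, a kinase of T cell receptor signalling, had 2 and 8 (exact binomial test, adjusted p = 0.0473 over all genes and 0.00141 adjusted over the list alone) and was the 1 gene tested. The WT_Tex libraries had 51 and 52 regions at Fyn and the K215M_Tex libraries 50 and 35. Card11 had 1 of each kind. NF-kB members and targets had 17 and 12, a net share of 1.26% where random lists had 2.99% on average. The list thus lay below random lists, toward WT_Tex, and did not pass (permutation test, adjusted p = 0.436). Nfkb1 had 4 K215M_Tex-only regions and no WT_Tex-only region. Of the effector genes, Zeb2 had 4 K215M_Tex-only regions, Eomes had 4 WT_Tex-only regions, Ifng had 2 and 1 and Cx3cr1 had 1 WT_Tex-only region. That list had 10 and 8 (permutation test, adjusted p = 0.433). Cd8a had 1 WT_Tex-only region.

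Of 169 genes tested, 8 passed, all toward WT_Tex (exact binomial tests). No gene could have passed toward K215M_Tex, since the test is set against a K215M_Tex share of 70.5% and no gene had more than 10 group-specific regions. Even 10 of 10 would give p = 0.0399 by the exact binomial test, and the highest p called was 0.00224. Besides Tox and Fyn these were Cd69, an early activation and residency marker, with none against 5, Asap1 with none against 7, and Prkcb, a protein kinase C gene, with none against 6. Wwox had 1 against 7, and Dad1 and Nrip1 had none against 5. Adjusted p over the 8 genes ran from 0.00973 to 0.0473. Cd69 also passed adjusted over the list of tissue residency genes alone, as 1 of 2 tested. Toward K215M_Tex the lowest p belonged to Kank1, Ralgps1 and Rapgef4, with 9 regions against none each, and to Bnc2 and Dst, with 7 against none each. None of these 5 passed (exact binomial tests, adjusted p = 0.389 and 0.563). With the same number of peaks from every library, 1 gene passed, Fyn (exact binomial test, adjusted p = 0.0138), and Tox had an adjusted p of 0.123. With genes within 20 kb, 2 passed, Tox and Asap1, and Fyn had an adjusted p of 0.0584.

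The K215M_Tex libraries had 130 and 122 regions at melanoma genes and the WT_Tex libraries 100 and 97. The list, with 14 against 5 group-specific regions, did not stand apart from random lists (permutation test, adjusted p = 0.639). Myeloid genes had 5 and 1, B cell genes 1 and 2, natural killer cell genes 1 and 4, CD4 and regulatory T cell genes 6 and 4, fibroblast and endothelial genes 3 of each kind, and hepatocyte genes 2 and 1. The NFAT, NR4A, EGR and AP-1 family had 23 and 21, receptors 12 of each kind, tissue residency genes 14 and 17, interferon response genes 3 and 1 and cell cycle genes 9 and 1. None of these 12 lists passed (permutation tests, adjusted p from 0.111 to 0.908). Leaving out single libraries brought natural killer cell genes below the threshold in 3 of 4 cases, at 0.0408 without K215M_Tex replicate 1, 0.0378 without K215M_Tex replicate 2 and 0.00722 without WT_Tex replicate 2, and B cell genes at 0.0433 without WT_Tex replicate 1 (permutation tests). Y-linked genes had 7 peaks in each WT_Tex library and none in any other library, so the Tex groups as labelled also differ in Y-linked signal.

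The strongest single region of the K215M_Tex libraries against WT_Tex lay on chromosome X at 103481247 to 103482220, within Xist (103460373 to 103483233), the RNA gene of X inactivation. The next lay 20628 bp from Uprt on X, 59806 bp from Depdc1b, in Cables1 and 4827 bp from Gadd45g. Toward WT_Tex the strongest lay 1298 bp from Arid1a (chromosome 4, 133677254 to 133677710), with the authors' fold values of 6.58 and 6.72. Others lay in Pde2a, 64980 bp from Ret, 22198 bp from Bex3 and 39662 bp from Hdac4. By construction, leaving out a library raised these counts. K215M_Tex-only regions numbered 12728 without K215M_Tex replicate 1, 17268 without K215M_Tex replicate 2 and 12251 without WT_Tex replicate 1. WT_Tex-only regions numbered 5854 without K215M_Tex replicate 1, 6483 without WT_Tex replicate 1 and 8504 without WT_Tex replicate 2.

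K215M_Tex and WT_Tprime differ in both genotype and population as labelled. Neither group had a peak at the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d. The K215M_Tex libraries had 25154 specific regions and the WT_Tprime libraries 14368, against sums of 1306 and 988 for the mixed splits. K215M_Tex-only regions made up 63.6%, and 52.4% with the same number of peaks from every library (18205 against 16561). Card11 had 2 K215M_Tex-only and 14 WT_Tprime-only regions (exact binomial test, adjusted p = 0.00619, and 0.0846 with genes within 20 kb). Tox had 18 and 1 (adjusted p = 0.068 over all genes and 0.0114 adjusted over the list alone by the exact binomial test, and 0.0437 over all genes with the same number of peaks). Slamf6 had 2 and Tcf7 had 3 WT_Tprime-only regions, Pdcd1 had 2 and Cd8a had 1 K215M_Tex-only region, and Havcr2 had 1 of each kind. Stem-like genes had 42 K215M_Tex-only and 81 WT_Tprime-only regions (permutation test, adjusted p = 0.00425). Of their 10 tested genes, 1 passed over all genes and 4 passed adjusted over the list alone, Bach2, S1pr1, Satb1 and Bcl6. In all, 72 of 2455 genes passed, 18 toward K215M_Tex and 54 toward WT_Tprime (exact binomial tests), where 182 and 1402 genes had enough regions to reach the highest p called. Without K215M_Tex replicate 2 the K215M_Tex-only count was 38235, and without WT_Tprime replicate 2 the WT_Tprime-only count was 21934.

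Of the 7 lists of other cell types, 4 passed here. Melanoma genes had 77 K215M_Tex-only and 22 WT_Tprime-only regions and myeloid genes 14 and 48 (permutation tests, adjusted p = 0.0147 and 0.0017). Kit, a receptor that blood cell precursors carry too, was the 1 melanoma gene that passed adjusted over the list alone, and it ran the other way, with 1 and 8. Adgre1, Itgam and Flt3 of the myeloid list, Pax5 of the B cell list and Kdr of the fibroblast and endothelial list passed adjusted over the list alone, all toward WT_Tprime. B cell genes had 8 and 21 and natural killer cell genes 4 and 13 (permutation tests, adjusted p = 0.0174 and 0.0415). The natural killer cell list no longer passed with genes within 20 kb, with gene bodies and 10 kb, with the same number of peaks or without WT_Tprime replicate 1 (adjusted p = 0.0521, 0.0813, 0.153 and 0.0503, permutation tests). The other 12 lists did not pass (permutation tests, adjusted p from 0.0584 to 0.89). Among them, terminal exhaustion genes had 53 and 32, NF-kB members and targets 66 and 42, and CARD11 and T cell receptor signalling genes 55 and 58. The signalling list passed at 0.0202 without K215M_Tex replicate 1 and at 0.0106 without K215M_Tex replicate 2, and cytokine and chemokine receptors, with 33 and 43, passed at 0.0202, 0.0286 and 0.0176 without K215M_Tex replicate 1, K215M_Tex replicate 2 and WT_Tprime replicate 2 (permutation tests).

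**Figure D4:**
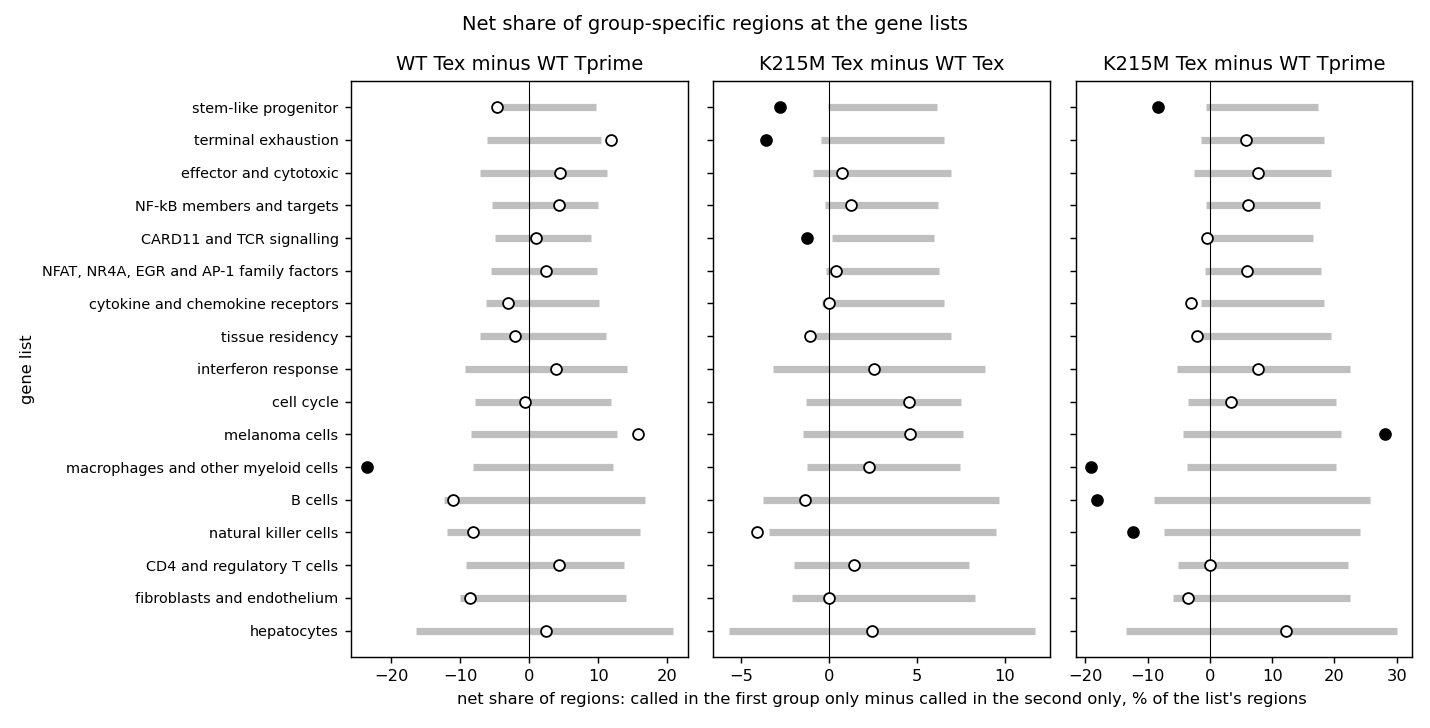
Net share of group-specific regions (x axis, % of a list's regions, first group minus second) for the 17 gene lists (y axis) in the 3 comparisons, whose x axes differ in range. Circles give the lists, filled where the adjusted p of the permutation test passed the 0.05 level, and grey bars span 2 SD either side of the mean of 10000 random lists. Myeloid genes lie at -23.6% for WT_Tex minus WT_Tprime, and the filled circles for K215M_Tex minus WT_Tex are the 3 lists that passed there, stem-like, exhaustion and signalling genes.

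The place of K215M_Tex between the wild-type groups was read from regions that separate WT_Tprime from 1 WT_Tex library, scored in libraries not used to choose them. Of the 16133 regions of both WT_Tprime libraries missing from WT_Tex replicate 2, 12.6% were called in WT_Tex replicate 1 (95% Wilson interval 12.1 to 13.2), and 14.9% and 11.8% in the K215M_Tex libraries. Of the 22806 regions of WT_Tex replicate 2 missing from both WT_Tprime libraries, 73.5% were called in WT_Tex replicate 1 (72.9 to 74.0), and 76.2% and 70.5% in the K215M_Tex libraries. With the roles of the WT_Tex libraries exchanged, the WT_Tprime regions were called at 7.07% in WT_Tex replicate 2 and at 11.9% and 9.32% in the K215M_Tex libraries. The WT_Tex regions were called at 60.2%, and at 73.6% and 67.6%. K215M_Tex lay 2.14 and 5.12 percentage points above the held-out WT_Tex libraries on average, less than the SD of 3.11 and 7.26. With the same number of peaks from every library the differences were -0.92 and -0.725 points. The first lay beyond its SD of 0.199 and the second within its SD of 0.925. Both had the opposite sign to the differences in the full lists. The WT_Tex values behind these SDs come from different sets of regions, and each K215M_Tex value is a mean over both sets. The SDs thus mix the choice of regions with the spread between libraries and serve as no test.

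Regions called in both WT_Tex libraries and in none of the other 4 numbered 1595. Independent lists of the same sizes, drawn from all 127935 regions, would share 368.9. In 100 simulations of unchanged groups against the same WT_Tex libraries the number was 343.2 on average and at most 386. Regions called in WT_Tprime and K215M_Tex and in neither WT_Tex library numbered 538, against 740.9 for independent lists and 51.21 in the simulations. The 1595 exceed both values and the 538 only the simulations. The simulations leave out real effects. The independent lists leave out that both sets behind the 1595 can hold only regions called in both WT_Tex libraries. Both sets behind the 538 can hold only regions called in neither. The values of 368.9 and 740.9 are thus too low as baselines, and part of the excess of the 1595 follows from the shared libraries. Its size beyond that cannot be read from these values.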

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

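The tests of carried-over melanoma cells, of carried-over myeloid or dendritic cells, of the list lengths behind the excess of K215M_Tex-only regions and of exchanged labels were chosen after their results were seen. The same holds for the test on regions opened in the T cells themselves. The T cell identity list was chosen after the data were seen, though its test was written before its result, and the value without genes of other lists was added later. The other 4 tests were written first.

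Peaks on chromosome Y lie outside the main comparisons, and there the genes Ddx3y, Eif2s3y, Uty and Kdm5d together had 7 peaks in each WT_Tex library, for a mean of 7, and 0 in the WT_Tprime and K215M_Tex libraries. Mice of different sex in the groups would give this pattern, and Xist, which is active in females, had at most 1 peak in a WT_Tex library against 3 and 3 in WT_Tprime and 4 and 2 in K215M_Tex. An exchange of the genotype labels between the Tex groups would not by itself give Y-linked peaks to 1 group. It would change only which genotype carries them, and a difference of sex can hold with or without it. Whether labels were exchanged stays open, since no peak list shows the Card11 mutation itself. The identifiers of 4 of the 4 Tex lists carry the other genotype. The Tex libraries whose identifiers say WT match WT_Tprime in lacking Y-linked peaks. Y-linked signal and genotype as labelled go together in the Tex groups, and Y-linked signal and population in the groups labelled WT. A difference of sex, if it is the cause, would go with them in the same way.

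Of the marker lists of other cell types, the myeloid list passed against both Tex groups and the melanoma list against K215M_Tex alone, in opposite directions. The B cell and natural killer cell lists also passed toward WT_Tprime, against K215M_Tex alone (permutation tests, adjusted p = 0.0174 and 0.0415). The natural killer cell list lost its call in 4 of 8 alternatives. The length of the lists is argued against as the whole cause, since with the same number of peaks from every library the melanoma and myeloid lists stayed at least 2.67 SD from random lists against both Tex groups. All 16 of 16 melanoma genes had a WT_Tex-only region, but the list missed the threshold against WT_Tex (permutation test, adjusted p = 0.0978), and Kit, with 1 WT_Tex-only and 6 WT_Tprime-only regions, and Gpnmb, with 1 and 4, ran the other way. Of the 22 myeloid genes, 17 had a WT_Tprime-only region against WT_Tex and 16 against K215M_Tex, and these counts, like those of the melanoma genes, describe the pattern without testing where the regions come from. Melanoma cells carried over into the Tex sorts cannot be told apart from regions opened in the T cells themselves. The same holds for myeloid or dendritic cells carried over into the WT_Tprime sorts. The 46 melanoma gene regions called in all 4 Tex libraries and no WT_Tprime library do not decide it either. A peak list does not show which cells a region comes from.

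K215M_Tex-only regions outnumbered WT_Tex-only regions, while 3 of the 10 lists not of another cell type passed toward WT_Tex. For the excess, the longer lists of the K215M_Tex libraries are a candidate explanation. With the same number of peaks it shrank to 52.7% of the group-specific regions, within the 51.8% and 57.3% of the mixed splits. Equal numbers of peaks draw both sides toward balance whatever the cause. The value therefore cannot tell longer lists from more open regions in K215M_Tex. For the T cell lists, the longer peak lists are argued against as the whole cause. With the same number of peaks the stem-like, exhaustion and signalling lists lay at -3.13, -2.52 and -3.61 SD from random lists. More melanoma chromatin in the K215M_Tex libraries may contribute. The 46 melanoma regions ranked at a median percentile of 34.3 and 41.6 by −log10 q in the K215M_Tex libraries. In WT_Tex they ranked at 17.4 and 14.5, a difference of 22.0. A lower share of T cell chromatin may contribute too. The T cell identity list lay -4.64 SD from random lists with the same number of peaks. Without the 10 of its 27 genes that belong to other lists it lay at -4.03 SD. The 7 lists of other cell types lay between -1.09 and 1.15 SD. As 1 more list of T cell genes, the T cell identity list cannot tell a lower share from a change within the T cells. An effect of the Card11 mutation on T cell chromatin stays open beside these explanations, and so do a difference of sex and the direction itself, given the conflict of labels.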

How the results depend on the processing

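The version on autosomes alone was chosen after seeing the data. For the 6 counts of group-specific regions, a −log10 q of at least 5, 50% of a region covered, windows of 500 bp around summits, every sequence, and autosomes alone moved no count by more than 1.5 times. With the same number of peaks from every library, K215M_Tex-only regions against WT_Tex fell from 6725 to 4250, and the other 5 counts moved by less than 1.5 times. The genes called between K215M_Tex and WT_Tex fell from 8 to 1 with the same number of peaks and to 2 with genes within 20 kb, which leaves fewer regions per gene. The cause of the first fall was not tested. In WT_Tex versus WT_Tprime, 22 of the 36 called genes stayed called with the same number of peaks and 26 with genes within 20 kb, and in K215M_Tex versus WT_Tprime 46 and 48 of 72. Leaving out each library in turn raised every count, since 1 library then decides for its group. WT_Tex-only regions against WT_Tprime ranged from 18796 to 27841 and WT_Tprime-only regions from 15167 to 21671. K215M_Tex-only regions against WT_Tex ranged from 9221 to 17268 and WT_Tex-only regions from 3900 to 8504. K215M_Tex-only regions against WT_Tprime ranged from 27256 to 38235 and WT_Tprime-only regions from 15434 to 21934.

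Of the 9 list results that passed, 7 passed in each of their 8 alternatives. The exhaustion list between K215M_Tex and WT_Tex lost its call in 1 and the natural killer cell list between K215M_Tex and WT_Tprime in 4. Of 336 alternatives of the 42 list results that had not passed, 15 passed. The held-out differences of K215M_Tex changed sign with the same number of peaks, from 2.14 and 5.12 points, both within their SD, to -0.92 and -0.725. No called list turned its direction relative to random lists. For genes, direction was checked only for the named genes that could be tested with the same number of peaks or with genes within 20 kb. None of these that was called turned its direction relative to all genes. The other called genes were not checked. Deviations of same-numbered libraries correlated at 0.00021 to 0.01, which shows no pairing by number but cannot exclude it. The mixed split with equal numbers together gave more regions than the other (1236 against 1118, 2880 against 2340 and 1306 against 988). Replicate 1 also had the longer list in each group. A replicate block, which asks for the same difference within both same-numbered pairs, gave the same regions by construction (16758 and 14094 for WT_Tex and WT_Tprime). The 5 motif alternatives were not run, since motifs need the genome sequence, and alternatives based on transcription starts used gene bodies. Unknown depth limits the comparisons, since a region missing from a list may be open and below the threshold of the calls.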

Other observations

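The lists reported here were chosen after the data were seen. Dendritic cell genes, a list of 24 of which 18 have a region called in all 6 libraries and 4 belong to another list, had 21 WT_Tex-only and 96 WT_Tprime-only regions (permutation test over genes, p = 0.0001, the smallest it can give). Against K215M_Tex they had 39 K215M_Tex-only and 92 WT_Tprime-only regions (permutation test, p = 0.0001). Between the Tex groups they had 17 K215M_Tex-only and 5 WT_Tex-only regions (permutation test, p = 0.703). Zfp366 and Flt3, both genes of dendritic cells, are among the genes called toward WT_Tprime in the comparison with WT_Tex. The WT_Tprime libraries had 20 and 20 regions at Zfp366, the WT_Tex libraries 4 and 2 and the K215M_Tex libraries 6 and 4.

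T cell identity genes, of which 27 matched the gene table and 10 belong to another list, had 83 WT_Tex-only and 35 WT_Tprime-only regions, and 76 and 39 with the same number of peaks from every library (permutation tests, p = 0.0881 and 0.0443). Between the Tex groups they had 11 K215M_Tex-only and 35 WT_Tex-only regions, and 5 and 44 with the same number of peaks (permutation tests, p = 0.0001 in both). Against WT_Tprime, K215M_Tex had 66 and WT_Tprime 52, and the order of the counts turned round with the same number of peaks, to 44 and 69 (permutation tests, p = 0.144 and 0.253). At the 217 regions of CARD11 and T cell receptor signalling genes called in all 6 libraries, the median percentile by −log10 q was 44.2 and 45.6 in the WT_Tex libraries and 41.0 and 37.6 in the K215M_Tex libraries, among the same set of regions.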
